A study of Mus musculus with 2 samples.

How the data were processed

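The series holds 2 paired-end RNA-seq libraries of poly(A) RNA from the mouse G1E line, 1 group with replicate numbers 1 and 2 taken from the labels. For each library the authors deposited a table per gene and a table per transcript, made on assembly mm10 with gene annotation M4 from a transcriptome alignment of that library alone, per the deposited descriptions. The aligner and the counting tool are not given in the sources used here, although the column names are those that RSEM writes.

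The deposited tables give expected counts, which are estimated read-pair counts in which reads shared between features are divided by a model, so they need not be whole. The authors' TPM values are abundances scaled by effective length and by the total of the library, per the file headers, and their FPKM values are fragments scaled by effective length and by the total of fragments. The tables also hold posterior mean versions of these deposited values and, per transcript, the percent of the gene's TPM given to it by the authors. Of the 43346 gene entries, 42462 (98.0%) were matched by Ensembl gene identifier, without its version, to a symbol, gene type and position in GENCODE M21, which is on the same assembly. The unmatched entries held 0.294% of the counts in replicate 1 and 0.267% in replicate 2, and they stayed in all counts of genes. The tables also list 97 spike-in entries, all at 0, and 26248 numbered entries of a median length of 73 bases, which held 0 counts in replicate 1 and 1 in replicate 2; both kinds were left out.

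Depth was 61982634 expected counts in replicate 1 and 80658648 in replicate 2. A count of 0 allows up to 3 counts, given as CPM of the library's total. Intervals for shares are exact 95% Clopper-Pearson intervals. Those for shares of counts, and the limits for counts of 0, cover counting error only, since read pairs without molecular identifiers are not independent molecules. Those for shares of genes treat genes as independent, which they are not.

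Levels are the deposited TPM, with mean and SD over the libraries. A gene counted as detected at 1 TPM or more in both. With a single group there was no comparison of conditions and none was tested. Medians of lists were taken on log2(TPM + 1), and each was placed among the medians of 10000 random lists of the same size drawn from protein-coding genes. Agreement of the libraries was measured by Pearson and Spearman correlation across genes and by the common biological coefficient of variation from edgeR 4.0.16 in R 4.3.3, on expected counts rounded to whole numbers, with TMM scaling (factors 0.960 and 1.04) and genes with 10 or more counts in at least 1 library. Intervals of the correlations and of the coefficient came from resampling genes. Differences between the libraries were tested per gene with a two-sided exact conditional binomial test on the rounded expected counts and TMM-scaled totals, with Benjamini-Hochberg adjustment, and called at adjusted p under 0.05 and at least 2-fold; where a library had 0 counts, 3 were used for the ratio. This test knows counting error only. Expected counts were called whole within 0.005. GC content and length are those of each gene's transcript of highest mean TPM, with GC content from the M21 sequences, and trends of the log2 ratio on them were removed by a lowess fit with a span of 0.3 (statsmodels 0.14.6). Other steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

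On simulated counts with the real means and depths, the exact test recovered 88.6% of genes changed 2.5-fold and 97.5% of those changed 4-fold (193 and 198 changed genes among 11455 and 11459 tested, replicate 2 against replicate 1), and it called 1 and 0 unchanged genes. The last counts give no rate of false calls for the real libraries, whose spread exceeded counting error, with a common coefficient of variation of 0.224. Simulated coefficients of variation of 0.1 and 0.3 were estimated as 0.100 and 0.304 over 11477 and 11446 genes.

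The 19 gene lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined, except where the text says that a choice came after seeing the data. The lists were transcription factors, GATA1-activated and GATA1-repressed genes, globins, haem and iron, red cell membrane, cytokine signalling, stem cell, megakaryocyte, mast cell, neutrophil and monocyte, lymphocyte, pluripotent cell, and fibroblast and endothelial markers, cell cycle, apoptosis, stress, histones and sex-linked genes. Named genes are any list member, the 20 genes of highest mean TPM, the 10 largest differences in each direction among genes called different between the libraries that matched a symbol (entries without a symbol, some with larger differences, are counted in the totals but not ranked), and 20 genes chosen for transcripts. The X-linked partners of the Y-linked genes were named with their test. Rmrp, Rn7s1, Gm42418 as part of that comparison, the genes named for effective length and the gene families of the closing section were chosen after their values were seen, and several other families were looked at and are not described. The list members Hbb-b1, Hbb-b2, Ahsp, Mcpt5 and H1f1 to H1f5 matched no symbol and were not analysed here, and some other members are counted in their lists but not reported here by name. Alternatives were posterior mean TPM, FPKM, other pseudocounts, detection thresholds and count filters, library totals and DESeq2 1.42.0 size factors as scaling, other error models and fold requirements, other list members, backgrounds and transcript definitions, and each library left out in turn. Removal of the GC trend, random lists matched on GC content and detection without pseudogenes and histones were added after seeing the data.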

Results

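RNA was measured in G1E, an immortalised mouse cell line that the labels describe as a Gata1- erythroid progenitor. Such cells are held at an early stage of red cell development because they lack the function of GATA1, the DNA-binding factor that drives erythroid maturation. The data were 2 paired-end libraries of polyadenylated RNA, numbered replicate 1 and replicate 2, and they formed 1 group. Replicate 1 held 61982634 expected counts over annotated genes and replicate 2 held 80658648. No other condition was part of the data analysed here, so the values are levels, ratios within a library and the agreement of the libraries. Values written as mean ± SD are over the 2 libraries (n = 2) and in TPM, the length-scaled abundance, unless another unit is given. The labels call the libraries biological replicates but cite 1 shared cell sample for both, so this spread may be technical.

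Gata1 RNA was present in both libraries labelled Gata1-. Its level was 47.3 ± 0.997 TPM (SD, n = 2), from 4694 expected counts in replicate 1 and 5771 in replicate 2, at percentile 72.1 of the genes detected at 1 TPM or more in both libraries. The gene (ENSMUSG00000031162.10) lies on the minus strand of chromosome X from 7959260 to 7978071 in mm10. Of its 3 annotated transcripts, ENSMUST00000033502.9 took 99.6% ± 0.226 (SD, n = 2) of the gene's TPM. Counts summed over a gene or a transcript do not show which exons the reads cover, so the level neither tests nor contradicts a disrupted coding sequence.

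Gata2, the paralogue that acts in early blood progenitors and whose product GATA1 replaces on many sites during maturation, stood far above Gata1. Gata2 (ENSMUSG00000015053.10, chromosome 6 from 88193891 to 88207032) was at 1013 ± 102 TPM, percentile 98.5 of detected genes. The ratio of Gata2 to Gata1 was 22.6-fold in replicate 1 and 20.2-fold in replicate 2, a log2 ratio of 4.42 ± 0.12 (SD, n = 2). Neither gene was called different between the libraries.

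The erythroid and haematopoietic transcription factors formed the only list with every member detected. All 35 were detected in both libraries, 31 of them at 10 TPM or more and 17 at 100 TPM or more. Zfpm1, which encodes the GATA cofactor FOG1, was at 1195 ± 51.2 TPM, and Tcf3, which encodes the E-protein partner of TAL1, at 1213 ± 147. The members of the complex that joins TAL1 to GATA factors were all present, with Tal1 at 246 ± 10.9, Lmo2 at 317 ± 85.1, Ldb1 at 453 ± 59.4 and Lyl1, a relative of Tal1, at 554 ± 2.13. The erythroid factor Klf1 was at 221 ± 38.6 and the repressor Gfi1b at 693 ± 75.5, while its relative Gfi1 was at 2.22 ± 0.283. Myc reached 812 ± 53.2, Myb 42.1 ± 7.62 and Spi1, which encodes the myeloid factor PU.1, 136 ± 4.47. The other members under 10 TPM were Sox6 at 1.88 ± 0.0141, Fli1 at 2.98 ± 0.707 and Erg at 2.00 ± 0.0636, the last pair being ETS factors of megakaryocytes and stem cells.

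**Figure D1:**
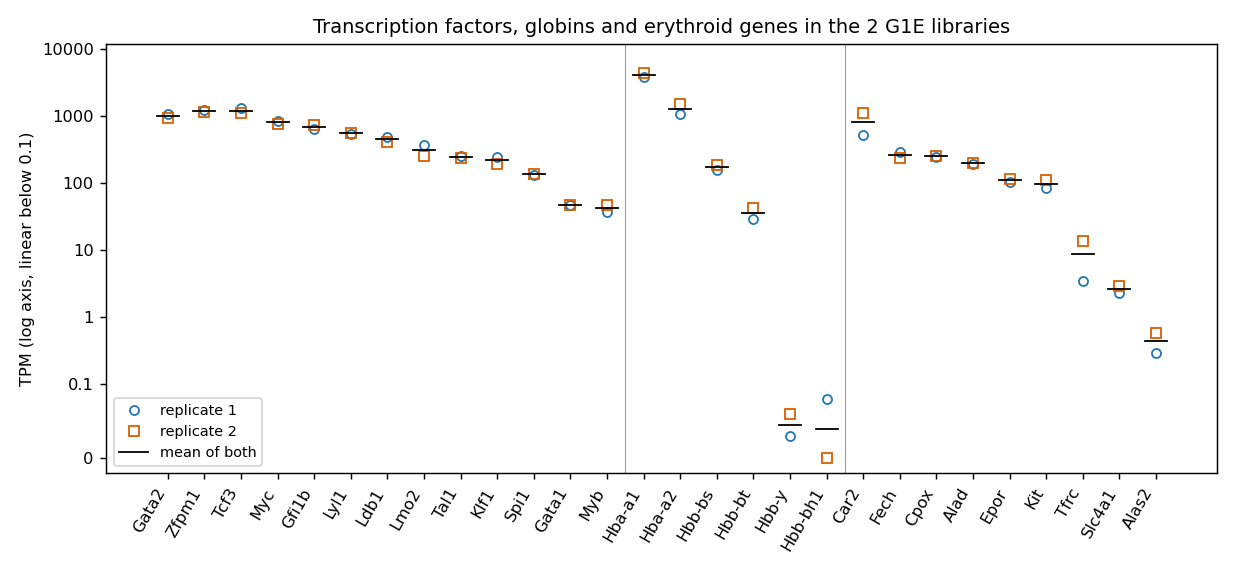
TPM (log axis, linear below 0.1) of transcription factors, globins and other erythroid genes in replicate 1 (circles) and replicate 2 (squares), with a bar at the mean of both. Gata2 at 1013 ± 102 TPM lies far above Gata1 at 47.3 ± 0.997, and the alpha globins lie above the beta globins.

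The next comparison set genes listed from textbook knowledge as falling when GATA1 is restored against genes listed as rising. Neither response was measured here. The 13 repressed genes had a median of 116 TPM in replicate 1 and 138 in replicate 2, and the 24 activated genes found in the annotation had 56.5 and 64.9. Among the repressed genes, Gata2, Myc and Lyl1 were highest, Vim was at 496 ± 74.8, Hhex at 271 ± 75.8, Ccnd2 at 206 ± 58.2 and Kit, the stem cell factor receptor, at 96.7 ± 18.9. Cd34 and Bcl2 stood apart from that list at 0.310 ± 0.0424 and 1.07 ± 0.134. The activated genes split widely. Hba-a1, Hba-a2, Zfpm1, Car2 and Gfi1b were highest, and for Car2 the level was 525 TPM in replicate 1 and 1129 in replicate 2, with effective lengths of 1059 and 794 bases. A further 8 members averaged below 5 TPM, among them Alas2 (0.435 ± 0.205), Slc4a1 (2.60 ± 0.424), Epb42 (1.02 ± 0.0707) and Btg2 (3.46 ± 1.66).

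The difference of the list medians on the log2(TPM + 1) scale, repressed minus activated, was 1.05 ± 0.03 (SD, n = 2). It exceeded the spread between the libraries, but random pairs of protein-coding gene lists of the same sizes gave a smaller difference in 81.3% of draws in replicate 1 and 80.3% in replicate 2. The size of the difference also depended on which members were used, and without the globins it was 1.69.

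Beta-like globin RNA was almost entirely of the adult type. Hba-a1 was at 4164 ± 399.7 TPM and Hba-a2 at 1296 ± 320.3, and the beta-like genes Hbb-bs and Hbb-bt were at 173 ± 21.3 and 35.7 ± 9.78. These 4 genes together made up 0.567% ± 0.0751 (SD, n = 2) of all TPM. The alpha genes exceeded the beta genes 26.1 ± 0.443-fold. The embryonic genes Hbb-y and Hbb-bh1 together held 3 of the beta-like globin counts in replicate 1 and 2 in replicate 2, which is 0.0667% (95% Clopper-Pearson interval 0.0138 to 0.195%) and 0.0285% (0.00345 to 0.103%). The log2 ratio of adult to embryonic beta-like globin TPM was 11.32 ± 0.83 (SD, n = 2), being 10.73 in replicate 1 and 11.91 in replicate 2, and it rests on those few embryonic counts. With 1 TPM added to each sum it was 7.59. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so the division of reads within each pair is uncertain.

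Haem synthesis genes were detected except for the gene of the erythroid entry step. Of the 24 genes for haem synthesis and iron handling, 23 were detected in both libraries and Alas2, the erythroid form of the first enzyme, was not. Alas1, the form used by most tissues, was at 8.10 ± 1.15, and most later enzymes were higher, with Alad at 197 ± 0.728, Cpox at 251 ± 7.50 and Fech, which inserts the iron, at 263 ± 35.4. Uros was lowest of the later enzymes at 2.38 ± 0.813. The ferritin chains Fth1 and Ftl1 were at 16935 ± 2175 and 6682 ± 301 and together took 2.36% ± 0.248 of all TPM. The transferrin receptor Tfrc was at 3.42 TPM in replicate 1 and 13.8 in replicate 2, values that rest on different estimated lengths, while its relative Tfr2 was at 61.1 ± 17.5.

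Red cell membrane and surface genes were partly expressed. Of 22 genes, 18 were detected in both libraries and 3 were below 1 TPM in both. Spectrin beta (Sptb) was at 163 ± 10.8, Epb41 at 133 ± 26.2, Add2 at 103 ± 7.75, Ank1 at 57.0 ± 9.85 and the glucose transporter Slc2a1 at 86.5 ± 9.46. The anion exchanger Slc4a1 was near 3 TPM, and the water channel Aqp1 was at 0.01 TPM. Bpgm was called higher in replicate 2, at 1.43 against 4.92 TPM.

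Among 21 cytokine receptor and signalling genes, 15 were detected in both libraries. Epor, the erythropoietin receptor, was at 109.7 ± 10.2, Il3ra at 46.7 ± 0.615, Csf2rb at 64.8 ± 0.113 and Lyn at 38.8 ± 1.90. The STAT5 targets Cish (154 ± 1.60), Socs2 (142 ± 8.34) and Pim1 (134 ± 19.2) were all above 100 TPM, as was Stat5a at 158 ± 0.233. The receptors Flt3, Il7r and Csf3r were each below 0.1 TPM.

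Most markers of other blood lineages and of other cell types were below 1 TPM, with the most detected members in the megakaryocyte list. Of 20 stem and progenitor markers, 4 were detected in both libraries, namely Gata2, Kit, Erg and Egfl7 (133 ± 5.85), while Cd34, Hoxa9, Mecom, Hlf and Ly6a were below 1 TPM. Of 18 megakaryocyte markers 8 were detected, led by Gp5 (33.0 ± 0.453) and Itga2b (25.5 ± 3.51), with Pf4 at 2.23 ± 0.276 and Vwf at 0.05 TPM. The mast cell and basophil list had 4 of 18 detected, namely Srgn, Il1rl1 (8.56 ± 2.45), Cpa3 (3.37 ± 0.0636) and Hdc (2.36 ± 0.410), and the neutrophil and monocyte list 4 of 24, namely Cebpe (11.7 ± 0.728), Cd68 (2.25 ± 0.0566), Prtn3 (2.03 ± 0.0283) and Mpo (1.64 ± 0.170). A single member was detected in each of the lymphocyte, pluripotent cell and fibroblast and endothelial lists: Lck at 1.58 ± 0.332, Dppa4 at 10.2 ± 1.73 and Eng at 5.76 ± 0.813. The genes Cd3e, Pou5f1, Nanog, Col1a2 and Pdgfra were at 0 TPM in both libraries.

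Most proliferation genes were expressed, and the inhibitors of the cell cycle were split. Of 33 cell cycle genes, 29 were detected in both libraries, with Cdk4 at 1775 ± 102, Rrm2 at 562 ± 93.0, Mcm2 at 424 ± 30.2, Ccnd3 at 433 ± 0.636 and Aurkb at 282 and 302 in replicate 1 and replicate 2. The list median was 36.2 TPM in replicate 1 and 78.4 in replicate 2, although the median log2 ratio of scaled counts was 0.11. The 4 undetected members were Ccnd1, Cdkn1c, Cdkn2a and Cdkn2b, each below 0.1 TPM, whereas the inhibitors Cdkn1a, a p53 target, Cdkn2c, Cdkn1b and Cdkn2d were at 169 ± 19.2, 56.1 ± 2.80, 34.4 ± 0.764 and 12.9 ± 2.07. The apoptosis list had 14 of 17 detected, including Mcl1 (341 ± 104), Bbc3 (277 ± 99.5), Bax (223 ± 39.1) and Trp53 (157 ± 26.1), while Bcl2l1, a survival gene that GATA1 activates, was at 73.3 ± 14.7. The stress and immediate early list had 12 of 17 detected, with Atf4 at 158 ± 16.7, Asns at 103 ± 0.771, Ier2 at 115 ± 3.33, Fos at 3.85 ± 0.318 and Hspa1a at 0.200 ± 0.0283.

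Set against 10000 random lists of protein-coding genes of the same size, the medians of 10 of the 19 lists lay in the highest 2.5% and none in the lowest 2.5%. These 10 were the transcription factors, both GATA1 lists, haem and iron, membrane, cytokine signalling, cell cycle, apoptosis, stress and histones. The medians of the megakaryocyte, globin, neutrophil, mast cell and stem cell lists lay at percentiles 73.8, 56.9, 52.3, 46.0 and 42.2, and those of the fibroblast and endothelial, sex-linked, pluripotent and lymphocyte lists at 16.3, 12.6, 12.5 and 12.4 (mean of both libraries). These percentiles describe these libraries and are not tests. The lists at 12.4 to 16.3 had medians of 0 TPM, which tie with many random medians, so they could not reach the lowest 2.5%. With posterior mean TPM the fibroblast and endothelial list was at 0.955, inside the lowest 2.5%. The lymphocyte, pluripotent and sex-linked lists were then at 6.27, 7.9 and 34.4. Among only the genes detected in both libraries, the haem and iron, membrane and histone lists fell to percentiles 91.7, 89.9 and 47.1, the 4 detected globins and 4 detected stem cell markers rose to 99.9 and 97.7, and the detected megakaryocyte, mast cell and neutrophil and monocyte markers were at 3.08, 9.46 and 0.440, the last in the lowest 2.5%. Matched on GC content the histone list was at 96.0, an alternative chosen after seeing the data.

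**Figure D2:**
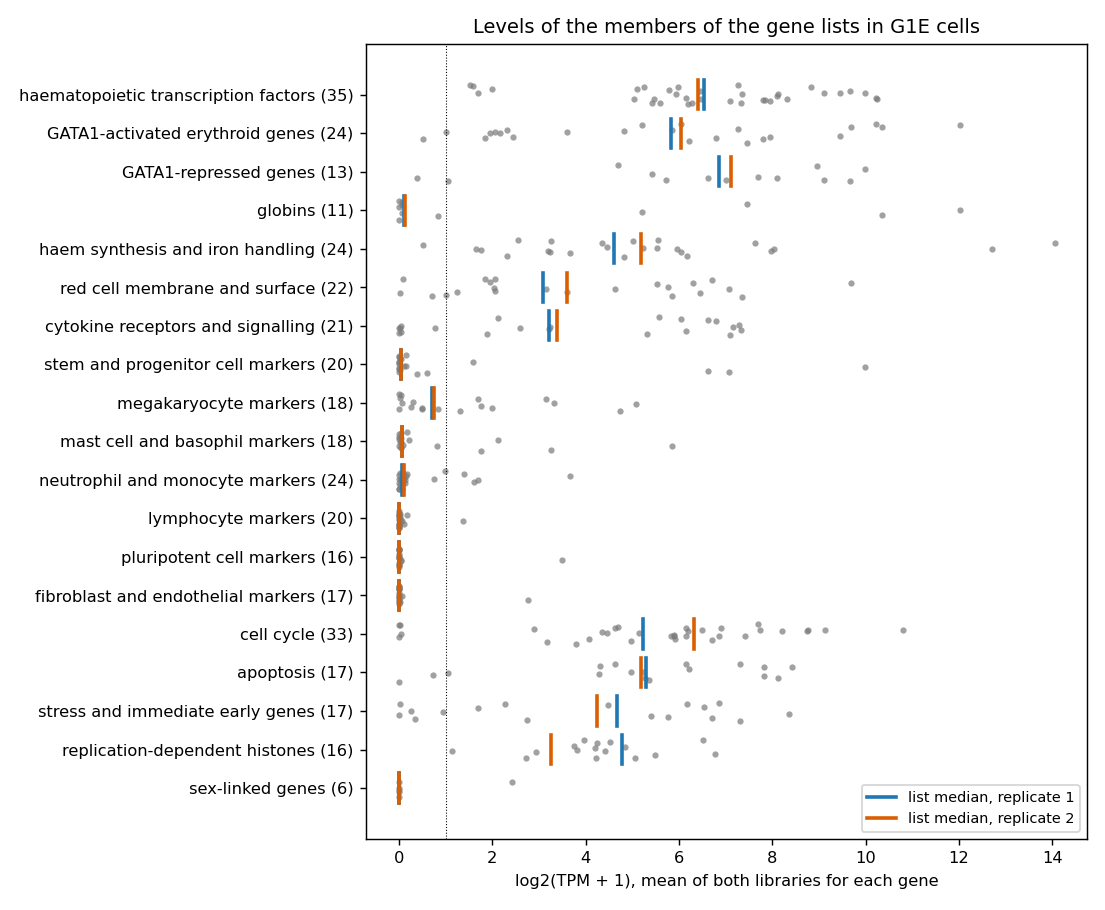
Level of each member of the 19 gene lists as log2(TPM + 1) of its mean over both libraries (grey points; number of members found in parentheses), with the list median in replicate 1 and replicate 2 as vertical bars and a dotted line at 1 TPM. All 35 transcription factors lie to the right of the line, and most markers of lymphocytes, pluripotent cells, fibroblasts and endothelium lie at 0.

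Ribosomal protein genes were the largest group among the most abundant genes. In all, 9150 genes were detected at 1 TPM or more in both libraries, of which 8581 were protein-coding among the 21474 protein-coding genes in the tables. The 20 genes of highest mean TPM held 11 ribosomal protein genes, led by Rplp1 at 48011 ± 5353 TPM, 3 histone genes, both ferritin genes, the glycolytic genes Gapdh (28428 ± 2681) and Aldoa (6634 ± 147), Ptma and Gm42418, which is annotated as a lincRNA. The single most abundant gene took 4.80% ± 0.535 of all TPM, the first 10 took 18.5% ± 1.36 and the first 100 took 47.0% ± 1.01 (SD, n = 2). By class, 82 ribosomal protein genes took 21.6% ± 0.722, the replication-dependent histones 4.26% ± 1.05 and the mitochondrial genome 1.01% ± 0.0347. Levels followed base composition in both libraries. Detected protein-coding genes with a GC content of 46.3% or less, 1700 genes, had medians of 6.09 and 7.50 TPM, and the 1700 with 57.4% or more 43.1 and 41.5. Across 8500 such genes, which are not independent replicates, Spearman's rho between GC content and TPM was 0.398 in replicate 1 and 0.364 in replicate 2. Among named genes the leading transcript had a GC content of 39.8% for Tfrc, 44.3% for Top2a and 58.2% for Gata2. Not all named genes followed the trend, as Gfi1 had 66.2% at 2.22 TPM and Cpox 47.7% at 251 TPM.

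The last comparison asked how far the 2 libraries differed. Replication-dependent histone genes were higher in replicate 1: of 60 tested, 50 were called higher there and none in replicate 2, with a median log2 ratio of replicate 2 to replicate 1 of -1.88. Summed over the class, which depends little on how reads are divided between its members, TPM was 49954 against 35150, a ratio of 1.42. Of these sums Hist1h2ao and Hist1h2ap together held 31977 and 25243 TPM, so the ratio rests mostly on that pair. The sums are in TPM and the median is over scaled counts of single genes, so their sizes are not directly comparable. Several other classes of RNA that lack a poly(A) tail leaned the same way, to differing degrees. Median log2 ratios were -2.55 for ribozymes, -1.35 for misc_RNA and -0.26 for small nucleolar and Cajal body RNAs. The 1 tested small nuclear RNA was at -0.98 and was not called. All 3 tested ribozymes were called higher in replicate 1, of 9 tested genes of the class misc_RNA 6 were called higher in replicate 1 and 1 in replicate 2, and of 9 small nucleolar and Cajal body RNAs 2 and 1. Rpph1, the RNA of ribonuclease P, was at 501 against 52.4 TPM in replicate 1 and replicate 2. Rmrp and Rn7s1 were chosen after their values were seen, with Rmrp at 461 against 90.5 and the signal recognition particle RNA Rn7s1, which shares its reads with the copy Rn7s2, at 1852 against 635. Gm42418, which is annotated as a lincRNA and so was not counted in these classes, was at 15791 against 4969 TPM. Called higher in replicate 2 were Srgn (log2 ratio 2.22), Bpgm (1.68), Mcm7 (1.46), Aurka (1.07) and Trim10 (1.06).

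In total, 654 of 11636 tested genes were called different by an exact conditional binomial test on the rounded expected counts (Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold), 444 higher in replicate 2 and 210 higher in replicate 1. None of the 35 transcription factors was among them, and of the 33 cell cycle genes Aurka and Mcm7 were, while that list's median log2 ratio was 0.11. Across the 19 lists, 23 members were called after adjustment over all genes tested and 23 when adjusted over the list alone, 13 of them among the 16 histone genes of the fixed list. The others included Gzmb and Mcpt1 of the mast cell list, higher in replicate 2, and Hoxb4, Gp1bb and Treml1 of the stem cell and megakaryocyte lists, higher in replicate 1, all of which averaged below 1 TPM. The test compares these 2 libraries and knows counting error only. edgeR's negative binomial exact test called 114 genes, 56 higher in replicate 2 and 58 higher in replicate 1, with a dispersion estimated from these same 2 libraries, so it holds no independent error. With no fold requirement the exact conditional test called 7495 genes, 3747 higher in replicate 2 and 3748 higher in replicate 1. TMM scaling centres the ratios, which pulls so wide a set toward an even split, so this says little on the excess in replicate 2. A minimum of 50 counts gave 312 higher in replicate 2 and 109 in replicate 1, and a 4-fold requirement gave 96 and 73. Scaling by library totals alone shifted the median gene from a log2 ratio of 0.01 to one of 0.13 and gave 598 higher in replicate 2 and 170 higher in replicate 1.

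Among called genes that matched a symbol, the 10 largest differences in each direction were mostly in genes to which shared reads had been divided. Of these 20 genes, 12 were pseudogenes and 3 had whole expected counts in both libraries. A whole count shows no fraction of a read, but the model can also give all shared reads to 1 copy. Hist1h4m had 492 expected counts in replicate 1 and 0 in replicate 2, and Trim17 had 1442 and 27.9. Rsc1a1 had 0 and 244, and the pseudogene Gm12481 6.29 and 499.7. The 3 with whole counts were Calca, with 15 and 1 counts, Naprt, with 1 and 20, and Wdr93, with 1 and 26. The abundant histone genes Hist1h2ao and Hist1h2ap, which belong to a multigene family and are uncertain one by one, differed in opposite directions (21532 to 7643 and 10445 to 17600.5 TPM from replicate 1 to replicate 2) while their sum went from 31977 to 25243.

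Across all 43346 genes, log2(TPM + 1) correlated between the libraries with Pearson's r = 0.994 and Spearman's rho = 0.927, and across the 9150 detected genes with r = 0.981 and rho = 0.977. Genes are not independent replicates. Of the detected genes, 86.6% differed by at most 1.5-fold in TPM + 1. The common biological coefficient of variation was 0.224 (bootstrap interval over genes 0.216 to 0.231). A chi-square statistic of 271 per degree of freedom over genes with 20 or more counts was far above that of 1 library deposited under both labels, and it says nothing on whether the remaining spread is biological or technical.

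**Figure D3:**
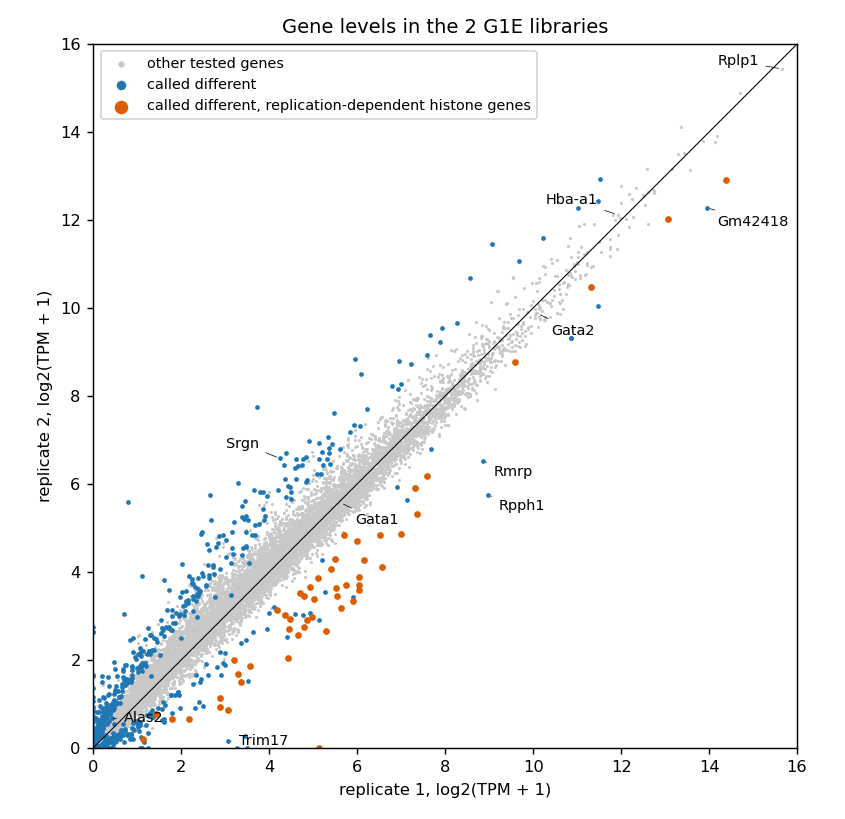
log2(TPM + 1) of the 11636 tested genes in replicate 1 (x axis) and replicate 2 (y axis), with genes called different in blue, called histone genes in orange and the line of equality. The called histone genes lie below the line, on the side of replicate 1.

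The leading transcript was compared between the libraries. Among 6599 detected genes with more than 1 annotated transcript, the most abundant transcript was the same in both libraries for 5729, or 86.8% (95% Clopper-Pearson interval 86.0 to 87.6%). In the other 870 genes that transcript took a median of 51.5% of the gene in replicate 1. Single transcripts took most of Zfpm1 (97.2% ± 2.40), Runx1 (95.1% ± 0.665), Gfi1b (92.9% ± 0.566), Kit (90.1% ± 2.36) and Pkm (99.7% ± 0.0566). The leading transcript took 83.4% ± 6.5 of Gata2 and 70.2% ± 12.4 of Tal1. That of Bcl2l1 took 88.6% in replicate 1 and 57.0% in replicate 2. The leading transcript of Alas1 was ENSMUST00000143125.1 in replicate 1, at 38.4%, which is annotated as a target of nonsense-mediated decay. In replicate 2 it was the protein-coding ENSMUST00000141118.3, at 64.9%. Such shifts moved gene levels too. For Tfrc the effective length fell from 4299 bases in replicate 1 to 1867 in replicate 2, and its TPM ratio was 4.04 although its scaled counts did not differ by 2-fold (log2 ratio 0.65). Of 496 detected genes whose TPM differed by 2-fold or more, 70 had effective lengths that differed by 1.5-fold or more.

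The labels give the sex of the line as male, and 6 sex-linked genes were read as a check. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in both libraries, which allows up to 0.0484 CPM in replicate 1 and 0.0372 in replicate 2. Their X-linked partners were expressed, with Ddx3x at 19.4 ± 5.78, Eif2s3x at 26.4 ± 8.16, Kdm5c at 69.1 ± 4.19 and Kdm6a at 7.77 ± 0.113. Xist, the RNA of the inactive X chromosome, had 1 count in replicate 1 and 7 in replicate 2, and its antisense partner Tsix was at 4.34 ± 0.962.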

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

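Of 63 alternative values, 47 moved by less than the spread between the libraries, stayed within 1.5 times for counts, or, for correlations, the coefficient of variation and the leading transcript, stayed within the resampling or Clopper-Pearson interval. Among these, the 10 levels, ratios and shares with a library left out were bound to do so, since with 2 libraries the mean then moves by less than the SD, and they show no stability. The same holds for Spearman's rho with other pseudocounts, which keep the order of genes. It also holds for the Gata2 to Gata1 and globin log2 ratios as FPKM, a fixed fraction of TPM within a library. The other 16 of the 63 moved further, and none of the log2 ratios or list differences changed sign. Removing the GC trend, matching random lists on GC content and leaving out pseudogenes and histones were chosen after seeing the data. As FPKM the Gata1 level was 42.1, since FPKM is a fixed fraction of TPM within a library. The adult to embryonic globin log2 ratio was 7.59 with 1 TPM added to each sum, which caps a ratio over a near-zero value. The log2 difference of repressed and activated lists (SD, n = 2) was 1.69 ± 0.27 without globins and 1.40 ± 0.28 without the transcription factor genes. With means in place of medians it was 0.88 ± 0.17. Among protein-coding nuclear genes alone the first 100 took 48.2% of TPM. Pearson's r was 0.988 with a pseudocount of 0.01 and 0.978 over genes at 1 TPM or more in at least 1 library, where Spearman's rho was 0.976. The coefficient of variation was 0.236 with library totals alone. The count of genes differing between the libraries was 421 with a minimum of 50 counts, 7495 with no fold requirement (3747 higher in replicate 2 and 3748 in replicate 1), 169 at 4-fold (96 and 73) and 114 with edgeR's negative binomial exact test, whose dispersion came from the same 2 libraries (56 and 58). The excess of genes higher in replicate 2 was absent with edgeR's test and with no fold requirement. In the latter case TMM scaling pulls the split toward even, so it says little on the excess. Library totals alone gave 768, DESeq2 size factors 645, no count filter 666 and removal of the GC trend 541, of which 516 were among the 654. The leading transcript was shared by 88.8% of genes at 10 TPM or more, and by 60.1% when it had to take 60% or more in both libraries. For the values whose construction does not show it, the cause was not tested.

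The count of genes detected ran from 6780 at 5 TPM to 11243 at 0.1 TPM, and was 8799 without pseudogenes and histones. With each library left out in turn, Gata1 was at 46.6 to 48.0 TPM, the log2 ratio of Gata2 to Gata1 at 4.34 to 4.50, the adult to embryonic globin log2 ratio at 10.73 to 11.91, the list difference at 1.03 to 1.07, the share of the first 100 genes at 46.3 to 47.7%, the genes detected at 9287 to 9468, and the number of lists in the highest 2.5% of random medians at 10 in both. No paired analysis was possible because there is 1 group. Depth limits the embryonic globins, with 3 and 2 counts.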

Other observations

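Gene families outside the fixed lists, chosen after their values were seen, held both expressed members and members at or near 0 TPM. Some lay close to the 1 TPM threshold, such as Sox17 at 1.01 TPM in replicate 1 and 0.82 in replicate 2. Of 6 Gata genes, Gata3 was detected beside Gata1 and Gata2, at 18.0 ± 0.389 TPM (SD, n = 2). Of 17 Klf genes 9 were detected, with Klf1 highest and Klf16 next at 122 ± 23.2. Of the 4 Id genes, which encode inhibitors of E-proteins such as TCF3, Id1 was at 109 ± 1.73 and the others were at 0.02 TPM or less. Among 19 Sox genes, Sox12 (61.2 ± 0.884), Sox21 (9.94 ± 1.15) and Sox6 were detected. Of the Dnmt3 genes for new DNA methylation, Dnmt3b was at 30.1 ± 3.77 and no other passed 0.04 TPM, while Tet3 was at 54.1 ± 21.1 and Tet2 at 2.29 ± 0.382. Of 25 glycolysis genes 18 were detected, together at 4.58% ± 0.448 of all TPM, with Ldha at 2069 ± 60.1, Pkm at 2069 ± 312 and Tpi1 at 1827 ± 486 after Gapdh and Aldoa. Pklr, the red cell and liver pyruvate kinase, was at 59.4 ± 31.2.

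The Hox clusters, also looked at after their values were seen, differed from each other. None of 11 Hoxa genes reached 1 TPM in both libraries, and the highest was at 0.11 TPM. Of 9 Hoxc genes on chromosome 15, 5 were detected, with Hoxc4 at 62.8 ± 2.90, Hoxc6 at 27.8 ± 0.552, Hoxc5 at 11.8 ± 0.891, Hoxc8 at 11.1 ± 1.27 and Hoxc9 at 10.9 ± 1.36. Of 10 Hoxb genes Hoxb13 alone was detected, at 93.3 ± 1.26 from 10647 and 13714 expected counts, and of 9 Hoxd genes Hoxd4 alone, at 12.5 ± 2.28.

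Of the tests that follow, those on RNA without a poly(A) tail and on cells in S phase were chosen only after the result was seen. The design holds 1 group, so it gives no biological difference between the libraries to test.

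The 444 genes higher in replicate 2 were weighed against GC content, transcript length and reads shared between copies. After the trend on GC was removed, 343 of the 436 with a GC value, 78.7% (exact 95% interval 74.5 to 82.4%), were still called in that direction, or 77.3% of all 444; the bound set beforehand for excluding GC as the whole cause was 75%, and the interval extends just below it, while the bound for GC as the cause was fewer than 50%. After the trend on length was removed 96.8% were still called. Whole expected counts in both libraries were found in 67.6% of these genes, against 86.6% of the tested genes that were not called. Counts with a fraction of a read were thus over-represented here, and divided reads may contribute. A whole count does not exclude shared reads, since the model can give all of them to the same copy. GC and length therefore each leave most of these differences unaccounted for. How far shared reads account for them cannot be told from whole counts, and the source of the differences stays open. The cell cycle list, considered as a further explanation only after its value was seen, had a median log2 ratio of 0.11, or 0.09 with the GC trend removed.

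The 210 genes higher in replicate 1 include 50 replication-dependent histones. Removal of the GC trend left 173 of the 206 with a GC value called, 84.0%, or 82.4% of all 210, which argues against GC as the whole cause. More cells in S phase in the replicate 1 culture would raise replication genes with the histones. The 10 replication genes had a median log2 ratio of replicate 2 to replicate 1 of 0.23 (bootstrap interval -0.23 to 0.59). Of these 10 genes, 4 were below 0. The interval lies above the bound of -0.5, but that bound was set after the result was seen. A smaller shift toward S phase stays within the interval, so the test cannot decide whether S phase contributed. Whole counts were found in 42.4% of these genes and 24.8% were pseudogenes, against 85.1% and 5.24% of all tested genes. Divided reads therefore stay open as an untested explanation for many of them. RNA without a poly(A) tail made up 61 of the 210 genes, 29.0%, against 84 of the 11636 tested genes, 0.722%. It made up 2 of the 444 genes higher in replicate 2. Its carry-over into the replicate 1 library may account for that part of the 210 genes. Whether it accounts for the pattern cannot be told apart from other causes because most of the called genes belong to other classes.

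The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in a line labelled male. Depth argues against missed reads, since their X-linked partners held 59790 expected counts over both libraries. Reads given to the partners are also argued against, since 0.0399% of the 50-base words of the Y-linked transcripts occur in the partner's transcripts. All genes on chromosome Y together held 3.99 expected counts in replicate 1 and 3.34 in replicate 2. Loss of the Y chromosome from the cultured cells, and a label that does not describe these cells, both stay open as hypotheses, and no biological explanation was tested.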
